A study of Drosophila melanogaster with 2 samples.

How the data were processed

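Chromatin from whole prepupae carrying a CG15336-eGFP transgene was sheared by sonication to 200 to 800 bp and precipitated with an anti-GFP antibody, per the labels. The 2 libraries are separate biological replicates of 1 group. The deposited peak lists use the dm6 assembly, per the labels. The aligner, the peak caller and its version are not given in the sources used here, and the control named in the labels was not used here. Peaks were called by the authors on each replicate and on both together, per the deposited listings, and each kind is deposited as a ranked list and as a list past a threshold on the irreproducible discovery rate (IDR). For both replicates together a conservative and a less strict thresholded list exist.

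The signal of each peak is the authors' value, on a scale that is not stated, and it was used to describe and rank peaks, to compare promoter with distal peaks within a list, and to correlate matched peaks between the replicates; levels were not compared between lists. The deposited score is, from its values, a scaled IDR with a cap, and the lowest score in the thresholded lists was 830. The deposited ranked lists give the -log10 of the global IDR, and each thresholded peak had at least 2.00, which is an IDR of 0.01. For that reason the planned restriction to an IDR of 0.01 removed no peak. The pooled ranked lists also hold 16 unnamed columns of values per replicate, which were not used. Read depth cannot be read from peak lists, so the precision of shares was given as Wilson 95% intervals over peaks or genes.

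Coordinates are 1-based. The reference was Release 6 of the genome, whose arm lengths match dm6, with the Ensembl release 115 annotation without transposable elements, which held 13968 protein-coding genes on the arms. Gene list names were matched by symbol or synonym, and 4 were not found. A promoter peak had its summit within 500 bp of a transcript start. Summit annotation outside that window was taken in the order 5′ untranslated region, 3′ untranslated region, coding sequence, noncoding exon, intron, intergenic.

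Replicates were compared by overlap of at least 1 bp, with chance from 1000 shuffles within each chromosome. Promoter share and annotation classes were tested by permutation against 1000 shuffles, X density by an exact binomial test, gene lists and sequence motifs by Fisher's exact test, and promoter against distal signal by 100000 permutations. Motif windows reaching 50 bp to each side of the summit were compared with 5 background windows per peak, matched to within 5 percentage points of GC and on position relative to a start. Ratios to matched random lists have 0.5 added to both counts. Adjustment was by Benjamini-Hochberg at 0.05. Lists, motifs, tests, the rules for naming genes and most alternatives were fixed before the data were examined. Annotation classes, gene types, splits by signal and summit GC were added after the data were seen. The named genes are CG15336, the genes at the 20 highest promoter peaks and the 5 highest distal peaks found in both replicates, and up to 4 members of each list with the highest signal at a start. Alternatives were other peak lists, each replicate alone, other windows, other chance models and other backgrounds.

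Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The code was tested on simulated data. With 5 lists planted at 5 times the odds in each of 200 draws, 95.7% of planted lists of 25 or more genes and 71.7% of smaller ones were called, and 0.708% of other lists were. Genes outside the planted lists all had the same chance of a peak in these draws, whatever their number of starts. The rates therefore do not cover calls that depend on the number of starts. Of 3 planted motifs, 3 were called. Each was planted in a larger share of windows than the rarer called motifs had, so detection of rare motifs is not covered. A planted X ratio of 1.5 was recovered as 1.47.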

Results

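CG15336 is a protein-coding gene of Drosophila melanogaster, known by its annotation number. Genome occupancy of a CG15336-eGFP fusion protein was profiled by chromatin immunoprecipitation and sequencing with an anti-GFP antibody in whole transgenic prepupae aged 2 days. The series held 1 group with 2 biological replicates, so the comparisons are between the replicates and between the peaks and the rest of the genome. No control library was analysed here, and read depth is unknown because the files hold peaks only. Replicate 1 gave 6678 peaks and replicate 2 gave 8219 peaks past the authors' reproducibility threshold, with a median width of 360 bp in each. The conservative list made from both replicates held 9295 peaks with a median width of 384 bp, which covered 3.03 Mb. Of these peaks, 5465 (58.8%) overlapped a thresholded peak of each replicate. Intervals given for shares cover counting error only, and p-values compare peaks or genes within these lists, not animals.

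The sites with the highest signal lay at or nearest to CG11050, CG13323, Ugalt and CG31668, and each of these ranked 7 or higher in both replicates. The highest peak of the conservative list, on 2L at 6612347 to 6613067 of dm6, lay in an intron of CG11050, 1021 bp downstream of the nearest transcript start. Its signal of 3609 ranked 1 in the conservative list and 1 in each replicate. The 41 bp at its summit, 2L 6612688 to 6612728, read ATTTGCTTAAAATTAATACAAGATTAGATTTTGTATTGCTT in the reference. Of the replicate 1 peaks, 5470 of 6678 (81.9%, Wilson 95% interval 81.0 to 82.8) overlapped a replicate 2 peak by at least 1 bp. Shuffled peaks gave 3.91%, with a one-sided permutation p of 0.001, the smallest that 1000 shuffles can give. In the other direction 5527 of the 8213 replicate 2 peaks on the chromosome arms were shared (67.3%, interval 66.3 to 68.3). With each list split by signal into 4 sets of equal size, 99.2% of replicate 1 and 98.7% of replicate 2 peaks in the highest set were shared, against 57.7% and 35.3% in the lowest set. Across 5256 matched peaks, which are not independent replicates, the signals had a Spearman rho of 0.826 (bootstrap 95% interval 0.814 to 0.835). The summits of matched peaks lay a median of 18 bp apart.

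**Figure D1:**
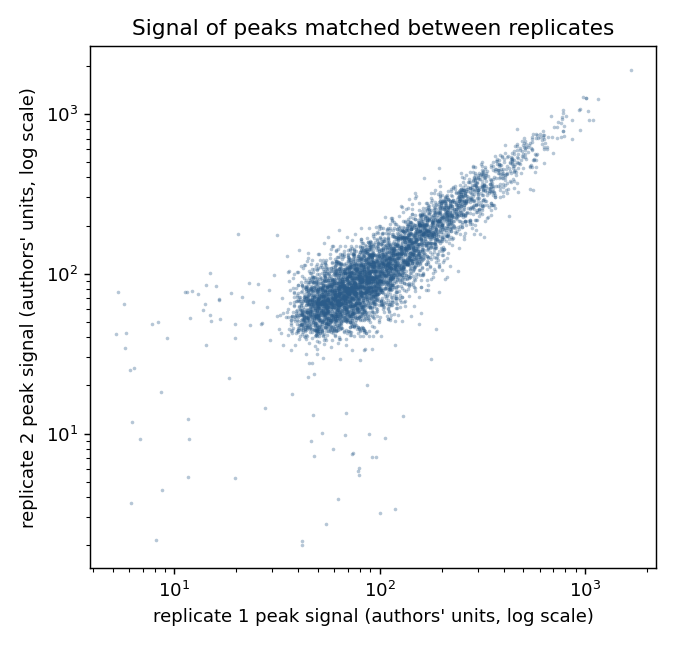
Signal of the 5256 peaks matched between replicates, in the authors' units on log axes, with 1 point per matched pair of peaks. The points follow 1 diagonal band (Spearman rho 0.826), with scattered pairs of low signal in either replicate.

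Peaks were concentrated just upstream of transcript starts and inside introns, and were nearly absent from coding sequence and transposable elements. Of the conservative summits, 3220 of 9295 (34.6%, Wilson 95% interval 33.7 to 35.6) lay within 500 bp of a transcript start, against 13.5% of shuffled summits. The replicates gave 32.9% and 38.2%, or 35.5% ± 3.76 (SD, n = 2). Of the promoter summits, 66.7% were upstream of the start, with a median position of -101.5 bp. The permutation test against 1000 shuffles was two-sided, with p = 0.002, the smallest it can give. With promoter windows as a class of their own, introns held 46.9% of all 9295 summits against 39.4% by chance. Intergenic sequence held 15.5% against 27.4%. These are shares of all summits, so a promoter share above chance leaves less for the classes outside it. Coding sequence held 31 summits (0.334%) where shuffling gave 13%, and 3′ untranslated regions held 0.882% against 5.04%. Annotated transposable elements held 18 summits (0.194%) against 5.79%. For each of these 5 classes the permutation p was 0.002, the smallest 1000 shuffles can give, and 0.00266 after Benjamini-Hochberg adjustment over 8 classes. The shares in 5′ untranslated regions (0.861% against 0.780%) and noncoding exons (0.914% against 0.816%) did not pass, with adjusted permutation p of 0.398 and 0.377. How reliably reads can be placed in repeats was not measured.

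**Figure D2:**
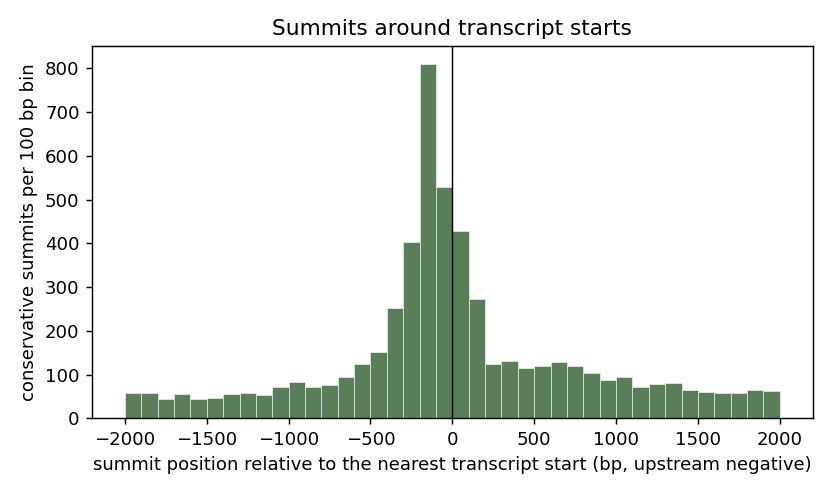
Number of conservative summits per 100 bp bin by distance to the nearest transcript start, with upstream positions negative. The tallest bin, 200 to 100 bp upstream, held 811 summits.

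Protein-coding genes and tRNA genes had peaks at their starts more often than shuffled peaks would give. Of 13968 protein-coding genes, 2980 (21.3%) had a summit within 500 bp of a start, against 8.21% by chance. Of 290 tRNA genes, 45 did (15.5%, interval 11.8 to 20.1), against 6.65%, and of 3289 noncoding RNA genes 356 did (10.8%), against 6.77%. For these 3 the permutation p was 0.002, the smallest possible, and 0.00466 after adjustment over 7 gene types. Small nucleolar RNA genes (5.95% against 6.61%), pseudogenes, small nuclear RNA genes and ribosomal RNA genes did not pass. A summit near the starts of several genes was counted for each of them. Whether the peaks at tRNA and noncoding RNA genes also lay at protein-coding starts was not tested.

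The 20 highest promoter peaks present in both replicates stood at Ugalt, which encodes a UDP-galactose transporter, CG18549, PNPase, Fkbp14, the glycolytic enzyme gene Gapdh2, CG1635, CenG1A, the tyrosine kinase gene Btk, the casein kinase gene gish, the Polycomb group gene ph-p, CG31145, CG14100, the small heat shock gene Hsp27, CG9147, SLC5A11, Chro, Tina-1, CG7601, CG31808 and Art3. Their signals ranged from 1362 to 2282. Their summits were upstream of the nearest protein-coding start at 17 genes and downstream at 3. Each peak was named by that nearest start, and some also lay within 500 bp of a start of another gene. The CenG1A summit was 398 bp from a start of mRpS23, and the Art3 summit 131 bp from a start of mRpS10. The Ugalt peak (X, 2703693 to 2704065) had its summit 41 bp upstream of the start, in intergenic sequence, with a signal of 2282. It ranked 6 in replicate 1 and 5 in replicate 2. The PNPase peak (3R, 31404487 to 31404832) had its summit in the 5′ untranslated region, 73 bp downstream of the start. The ph-p peak (X, 2136970 to 2137536) lay in an intron of the gene, 465 bp upstream of the nearest start, and ranked 16 and 23 in the replicates. The 5 highest distal peaks had signals of 1999 to 3609. Apart from the CG11050 peak, 1 lay 11914 bp downstream of the start of CG13323 and 1 lay 3776 bp downstream of the start of CG31668. Both of these were past the end of the gene, in intergenic sequence. The others lay in introns of CG12769 and of Trl, which encodes GAGA factor. The Trl peak (3L, 14759323 to 14759715) ranked 3 in replicate 1 and 19 in replicate 2.

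No peak of the conservative list lay at CG15336 itself (X, 8147949 to 8148705). The nearest summits were 4219 bp downstream of the gene, with a signal of 77.6, and 4251 bp upstream within CG17982, with a signal of 644.5. In the unthresholded list of replicate 2 a peak with its summit at 8148997, 292 bp past the gene and within CG10959, reached a -log10 IDR of 1.75, below the authors' threshold.

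Genes of the ecdysone response and the circadian clock had promoter peaks more often than other genes, and chemoreceptor, cuticle protein and testis-specific genes had them less often. Of 25 fixed gene lists, 4 were higher and 7 lower by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Among ecdysone response genes, 17 of 31 had a promoter peak (54.8%, Wilson 95% interval 37.8 to 70.8) against 21.3% of other genes, an odds ratio of 4.50 with adjusted Fisher exact p = 0.000278. The share was 15 of 31 in each replicate. The highest signals were at E23, an ABC transporter gene (1021), the nuclear receptor gene Eip75B (564.6), the cell death gene hid (337.7) and tai (305.7), which encodes a coactivator of the ecdysone receptor. In the circadian clock list 8 of 12 genes had a peak (odds ratio 7.39, adjusted Fisher exact p = 0.00381), including the kinase genes sgg (831.1) and dco (204.0), cry (301.4) and Pdp1 (214.7). Both lists were past the threshold in each replicate alone. Both lost the call against random lists matched on the number of transcript starts, with ratios of 1.57 and 1.87 and an adjusted permutation p of 0.0656 for each. The clock list was also lost with a 200 bp promoter window (odds ratio 2.94) and with peak intervals over the start (3.69).

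The share of cytosolic ribosomal protein genes with a promoter peak differed between the thresholded lists of the replicates. In the conservative list 41 of 91 had a promoter peak (45.1%, odds ratio 3.05, adjusted Fisher exact p = 3.65e-06), with the highest signals at RpL34b (283.8), RpS20 (237.5), RpL32 (229.6) and RpL23 (207.2). Replicate 2 gave 38 of 91 (odds ratio 2.86, adjusted Fisher exact p = 2.02e-05). Replicate 1 gave 14 of 91, an odds ratio of 0.986 with adjusted Fisher exact p = 1, so of the single replicates only replicate 2 passed. The difference between the replicates was not itself tested, and the ribosomal protein genes named above had peaks in each replicate. The list was also lost when the peaks were limited to a global IDR of 0.001 or less, with an odds ratio of 0.943. In the conservative list it kept the call against random lists matched on the number of starts (ratio 1.66, adjusted permutation p = 0.00167). It also kept the call with a 200 bp window (odds ratio 4.47) and by peak interval (4.90). Appendage and eye patterning genes were at 13 of 33 in the conservative list (odds ratio 2.40, adjusted Fisher exact p = 0.0400). They were not past the threshold in replicate 1 (6 of 33, odds ratio 1.21) or replicate 2 (10 of 33, odds ratio 1.72) alone. The odds ratio was 0.946 at an IDR of 0.001 or less. Against random lists matched on the number of starts the ratio was 1.35 (adjusted permutation p = 0.322). Their highest signals were at Dll (670.5), N (195.6), rho (133.2) and ptc (126.2).

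The 7 lower lists held 0 of 179 chemoreceptor genes, 3 of 121 cuticle protein genes, 1 of 43 testis-specific genes, 1 of 37 digestive protease genes, 3 of 51 odorant-binding protein genes, 0 of 22 salivary glue and late puff genes and 0 of 20 antimicrobial peptide genes. The chemoreceptor count of 0 allows a share of up to 2.10% (upper Wilson bound), with adjusted Fisher exact p = 7.09e-18. Adjusted Fisher exact p was 2.66e-08 for cuticle proteins and 0.00307 for the testis list. It was 0.00798 for proteases, 0.0165 for odorant-binding proteins, 0.0217 for glue genes and 0.0311 for antimicrobial peptides. Chemoreceptors, cuticle proteins and testis-specific genes were past the threshold in each replicate alone. The testis list, at an odds ratio of 0.0875, was lost with a 200 bp window (odds ratio 0.139, adjusted Fisher exact p = 0.0501) and by peak interval (odds ratio 0.175, adjusted Fisher exact p = 0.133). The other 4 were not past the threshold in replicate 1, nor were antimicrobial peptides in replicate 2. Those 4 also lost the call at an IDR of 0.001 or less and against lists matched on the number of starts, where they stayed below the matched lists. All 4 lost it by peak interval too, and all but odorant-binding proteins lost it with a 200 bp window. The ratios to matched lists were 0.248 for proteases and 0.356 for odorant-binding proteins, with adjusted permutation p of 0.0900 and 0.0656. For glue genes and antimicrobial peptides, with 0 genes each, the adjusted permutation p was 0.125 and 0.154. Among the 14 lists that did not pass, Polycomb and trithorax group genes had peaks at 11 of 27, with the highest signals at ph-p (1615), brm (693.3), E(z) (463.4) and Trl (454.9), and adjusted Fisher exact p = 0.0632. That list was past the threshold in each replicate alone, with odds ratios of 3.74 and 2.73. Insulator proteins had them at 7 of 17, led by Chro (1471) and Cp190 (821.4), with adjusted Fisher exact p = 0.122, and were past the threshold in replicate 1 alone (adjusted Fisher exact p = 0.0362). Mitochondrial ribosomal proteins (17 of 73), neuron markers (5 of 27), muscle markers (6 of 26), cell cycle genes (8 of 32), glial markers (4 of 12), fat body markers (6 of 17), haemocyte markers (4 of 15), heat shock genes (7 of 24), hormone synthesis genes (4 of 18), homeotic and segmentation genes (3 of 29), oxidative phosphorylation genes (11 of 86) and proteasome genes (4 of 32) did not pass.

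**Figure D3:**
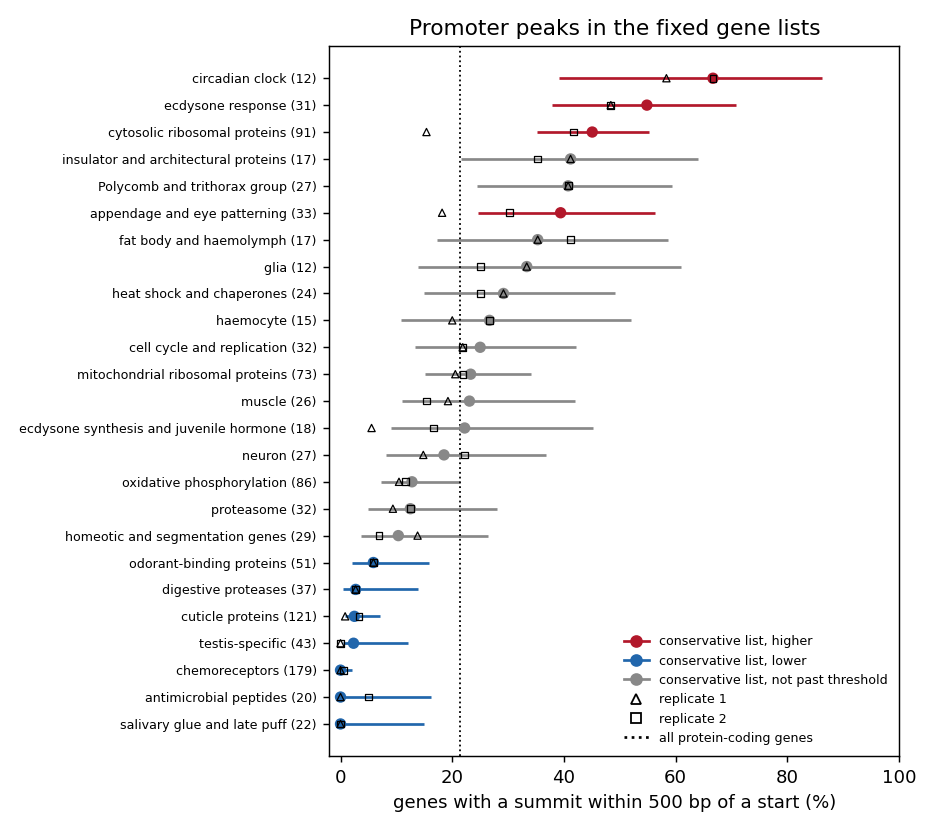
Share of genes with a conservative summit within 500 bp of a start in each of the 25 lists, with the number of members in parentheses and Wilson 95% intervals as bars. Triangles and squares give replicates 1 and 2, and the dotted line marks 21.3% of all protein-coding genes; the cytosolic ribosomal protein list is at 15.4% in replicate 1 and 41.8% in replicate 2.

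The X chromosome carried slightly more peaks per length than the autosomes. There were 77.5 peaks per Mb on X and 68.4 per Mb on 2L, 2R, 3L and 3R together, a ratio of 1.13 (interval 1.08 to 1.19, exact binomial test, two-sided, p = 2.44e-06). The replicates gave 1.20 and 1.11, or 1.16 ± 0.0573 (SD, n = 2). Counted over genes, 22.9% of X-linked and 21.2% of autosomal protein-coding genes had a promoter peak, a ratio of 1.08 that did not pass (Fisher exact p = 0.0789). The densities used whole arm lengths, and differences between arms in transposable element content were not taken into account. The labels give the sex of the animals as not collected.

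Summits carried GA-rich and CA-rich repeats and A tracts more often than background windows of the same GC content and position. GAGAG, the site of GAGA factor, was in 12.5% of windows reaching 50 bp to each side of the summit. Background windows held it in 8.56% of cases (odds ratio 1.52, adjusted Fisher exact p = 3.70e-29). The GAGAG odds ratio was 1.42 in replicate 1, 1.83 in replicate 2 and 1.24 at an IDR of 0.001 or less. The 8 bp GA repeat was in 1.56% against 0.435% (odds ratio 3.63, with 2.01 in replicate 1, 5.05 in replicate 2 and 1.72 against flanks 1000 bp away), runs of 8 A in 12.6% against 8.56% (odds ratio 1.54), and the CA repeat in 2.30% against 1.3% (odds ratio 1.78). Of 31 fixed motifs, 6 were higher and 5 lower. The higher ones included the su(Hw) core (odds ratio 1.74) and the ecdysone response element, which rested on 5 summit and 5 background windows (odds ratio 5.0, adjusted Fisher exact p = 0.0436). Its odds ratio was 25 in the less strict list, and it passed in neither replicate alone (1.00 and 2.5). The lower ones were the DRE (0.491), the BEAF-32 core (0.845), the Zelda site (0.741), the TEAD site (0.791) and the homeodomain site (0.908), as odds ratios. In replicate 1 alone the su(Hw), TEAD and homeodomain sites were not past the threshold, with odds ratios of 1.71, 0.834 and 0.919. The su(Hw) core was also lost at an IDR of 0.001 or less (odds ratio 1.16), with overlapping peaks reduced to the highest (odds ratio 1.52, adjusted Fisher exact p = 0.0871) and against flanks (odds ratio 1.63, adjusted Fisher exact p = 0.0887). Against flanks 1000 bp away, which were not matched on GC (41.9% against 33.9% at summits), GAGAG did not differ (12.2%, adjusted Fisher exact p = 0.602), and the homeodomain site was higher, not lower (odds ratio 1.42). There the CA repeat (0.889) and the DRE (1.13) turned direction without passing, and the BEAF-32 core (0.935) and the ecdysone response element (1.25) did not pass. Of all 6-mers, 262 were enriched, and those with the largest odds ratios in at least 5% of windows were AGAGAG (2.16), GAGAGA (1.99), GAGAGC (1.91), ACAGTG (1.74) and CAGTGC (1.73). Against flanks GAGAGC and CAGTGC did not pass (odds ratio 1.12 for each). The order depended on the window. With 100 bp to each side the odds ratios were 2.54 for CAGTGC, 2.47 for ACAGTG, 2.23 for GAGAGA, 2.12 for AGAGAG and 1.89 for GAGAGC.

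Summits were AT-rich, most of all those of the highest signal. Mean GC within 50 bp of the conservative summits was 33.9%, against 44.3% in windows centred 300 bp to each side and 42.4% at shuffled summits. The fall from flank to summit was 10.4 percentage points (SD over peaks 13.9), and 77.0% of summits lay below their flanks. The replicates fell by 13.3 and 9.06 points, and the mean difference was -11.2 ± 2.98 (SD, n = 2). In 4 sets of equal size by signal the fall was 16.2, 12.7, 9.51 and 3.21 points, from the highest set to the lowest. Summit GC was 18.8% to 34.7% at the 20 promoter peaks named above, with the lowest value at Btk.

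**Figure D4:**
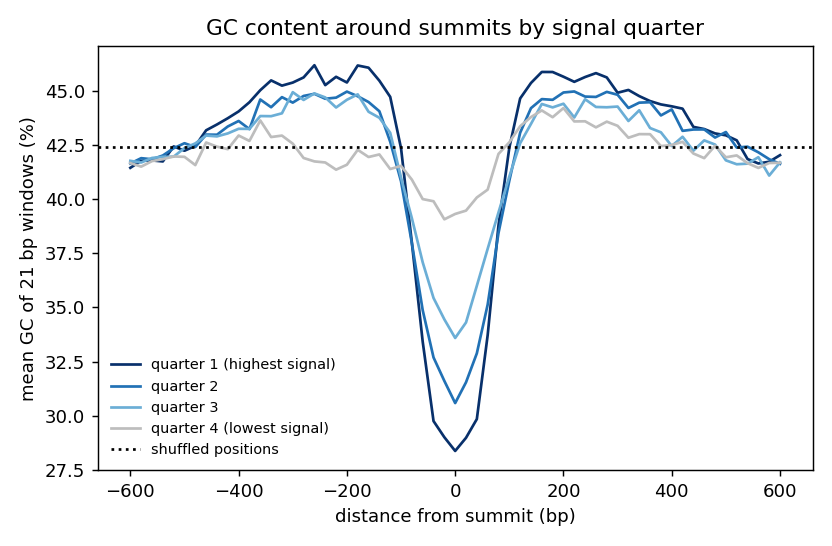
Mean GC of 21 bp windows by distance from the summit for conservative peaks in 4 sets of equal size by signal, with the dotted line at shuffled positions (42.4%). Each set dips at the summit, the highest set most and the lowest set least.

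Median signals of promoter peaks and distal peaks did not differ past the threshold in the conservative list, and the direction depended on the peaks used. The median was 122.2 for 3220 promoter peaks and 123.8 for 6075 distal peaks, a ratio of 0.987 (permutation test, two-sided, p = 0.491). The replicates differed in direction, with 1.03 in replicate 1 (permutation p = 0.150) and 0.944 in replicate 2 (permutation p = 0.00156). The difference passed in opposite directions under other choices, at 0.914 with a 200 bp window (permutation p = 2.0e-05), 0.952 in the less strict list (permutation p = 0.00722) and 1.08 at an IDR of 0.001 or less (permutation p = 0.0001).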

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

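The tests of the mitochondrial peaks and of summit GC were chosen only after those results were seen, and the test of the coding share after the shortfall was seen but with its prediction written before its own result. Replicate 2 held 6 peaks on the mitochondrial genome, in 4 regions, which no comparison used. Called peaks are not independent counts, and no control library was analysed here, so the number has no error of its own. The highest ranked 2 in that replicate, with a signal of 1533. The conservative list and the thresholded list of replicate 1 held 0. If the IDR threshold had kept such peaks out of replicate 1, its unthresholded list would hold some, and it held 0 among 44200 peaks. A difference in filtering or in mitochondrial DNA between the libraries stays open, and no biological explanation was tested.

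Summits were AT-rich in both replicates. The base composition of promoters is argued against, since distal summits fell by 12.2 percentage points from flank to summit and promoter summits by 7.0. With only the highest peak of each overlapping run kept, 8629 of 9295 peaks, the fall was 11.5, so it was present without the weaker overlapping calls. Too few peaks were removed for this test to have come out for weak calls on the sides of strong peaks. It therefore does not decide on that explanation. A GC bias of the sequenced fragments may contribute: over 250 bp to each side of the summit mean GC was 40.9%, against 42.1% to 42.3% in 20 shuffles, although that span includes the low summit itself and the flanks at 44.3% lay above the shuffled 42.3%. Background of the anti-GFP precipitation was not tested, and neither was a biological explanation.

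Few distal summits lay in coding sequence, 32 of 6075 (0.527%, Wilson 95% interval 0.373 to 0.743), counting any annotated coding base, also where it overlaps an untranslated region. Random distal positions matched on GC lay in coding sequence in 5.65% of cases, 10.7 times as often as the summits, and unmatched positions, taken outside promoter windows and peaks, in 16.8%. Low GC of the summits therefore does not account for the whole shortfall. Chromatin accessibility was not analysed here, and no biological explanation was tested.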

How the results depend on the processing

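The alternatives with an IDR of 0.001, with overlapping peaks reduced to the highest and with shuffles kept out of transposable elements were chosen after seeing the data. Peak overlap and promoter share kept their direction and side of the threshold under all alternatives run, at 70.5% to 98.5% and 22.0% to 45.5%. The highest overlaps, 97.3% and 98.5%, were with the longer unthresholded list of the other replicate. The lowest and highest promoter shares were with 200 bp and 1000 bp windows, where chance gave 6.15% and 23.6%. X density did so except over genes, at 1.08. The signal correlation was 0.715 for unthresholded lists, 0.846 as Pearson r of log2 signal and 0.837 for summits within 100 bp. The ratio of promoter to distal signal changed direction or side of the threshold. It was 0.952 in the less strict list, 0.914 with a 200 bp window, 1.08 at an IDR of 0.001 and 1.01 with overlapping peaks reduced, and 0.944 to 1.03 over the single replicates. The cause was not tested. Against 11 called gene lists there were 6 at an IDR of 0.001 (5 of them among the 11), 7 with a 200 bp window (6 shared), 6 by peak interval (5 shared), 4 against lists matched on starts (4 shared), and 7 to 10 in single replicates (5 and 9 shared). Against 11 motifs there were 21 with windows of 100 bp to each side (11 shared), 13 against flanks (4 shared) and 7 to 11 in single replicates (7 and 10 shared). Against 262 6-mers there were 146 at an IDR of 0.001, 462 against flanks, of which 135 were shared, and 416 with the wider windows. At an IDR of 0.001 the odds ratio was 0.946 for appendage genes and 0.943 for cytosolic ribosomal proteins, and the latter ran from 0.986 to 2.86 over single replicates. The ecdysone response element, at 5.0 in the conservative list, ran from 1.00 to 2.5 there. Against flanks the DRE was at 1.13, the homeodomain site at 1.42 and the CA repeat at 0.889. No paired analysis was possible because the design has 1 group. Read depth was not measured.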

Other observations

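Counted over whole genes, neuron markers and chemoreceptors held a summit less often than genes of similar length, and ribosomal protein genes of both kinds more often. All tests in this part were chosen after the data were seen, except that of 6-mers against flanks. With a summit counted from 500 bp upstream to the end of the gene, 6 of 27 neuron genes (22.2%) held one, against 60.2% in random lists matched on length (permutation p = 0.0002, the smallest 10000 random lists can give, and 0.00167 adjusted). Mitochondrial ribosomal proteins held one at 24.7% against 11.5% (adjusted permutation p = 0.0120). At promoters that list had 23.3%, against 21.3% of other genes not matched on length, and did not pass. For ecdysone response genes the values were 71.0% and 49.4% (adjusted permutation p = 0.0314). Of 25 lists, 3 were higher and 4 lower, and 3 in all were past the threshold at an IDR of 0.001 or less. Cytosolic ribosomal proteins were at 45.1% against 15.2% in the conservative list, but in replicate 1 alone at 15.4% against 11.5% (adjusted permutation p = 0.537). In replicate 2 alone ecdysone response genes did not pass (adjusted permutation p = 0.0514), and cuticle proteins passed in neither replicate alone (0.207 and 0.0514).

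Against flanks 1000 bp away, whose GC of 41.9% was not matched to the 33.9% at summits, the leading 6-mers were ATATTA (20% of summit windows against 8.83%), AATATA (24.4% against 11.4%), AAAATA (37.7% against 20.5%), TTTAAA (19.7% against 9.60%) and TATTAA (19.5% against 9.55%). A longer sequence, CACTGAGAGA, was in 85 of 9295 windows reaching 75 bp to each side of the summit (0.914%) and 18 of 18590 flanking windows (0.0968%). TCAGTGCA was in 203 (2.18%) and 113 (0.608%). Both were picked from these same windows, so their enrichment is not independent evidence.

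The 500 peaks with the highest signal had 52.6% of summits at promoters (Wilson 95% interval 48.2 to 56.9), the 1000 lowest 39.1% (36.1 to 42.2) and those between 32.9% (31.9 to 34.0). Of 396 peaks with a signal under 20, all among those 1000 lowest, 387 overlapped a stronger peak, against 276 of the 8899 others. Mean summit GC was 46.1% for these 396 peaks and 33.3% for the others. The promoter share of the lowest set was not computed without them.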
